A study of Mus musculus with 8 samples.

How the data were processed

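The samples were 8 mammary tumours of MMTV-PyMT mice on the FVB/N background, 4 from vehicle and 4 from SKI-606 mice, grouped by their titles in the labels. Per the labels' protocols, mice received SKI-606 by gavage (100 mg/kg), RNA came from each mouse, and labelling followed the recommendations of Affymetrix. The probe identifiers are those of the Mouse Genome 430 2.0 array. Replicates carry numbers 1 to 4 in both groups. The labels speak of RNA from each mouse, but do not list the animals. The p-values measure only the spread between these samples, which is technical in part if any samples shared an animal.

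The deposited values are linear ratios. The software that made the signals and the normalization are not given in the sources used here, and the scale was worked out from the values. In 26196 of 45101 probes (58.08%) the median over the 8 arrays was 1 within 0.0001, and in the other 18905 every value was a multiple of 1 step per array. This is what dividing each signal by the median of its array, and then by the median of its probe over the arrays, gives, with a constant divisor for probes whose median signal was below 10 and a lowest value of 0.01. Division by the probe median sets those 26196 probes to the same middle value, so for them the deposited file does not show which genes are bright. The signals before these divisions were therefore recovered as the smallest whole numbers that give the ratios, with a tolerance of 0.002 for a whole number, or of 3e-07 of the signal where that is more, and of 0.01 for the probes with a constant divisor. The recovered signals gave back all 45101 deposited probes (100.0%) within a relative 0.0001. On 5000 simulated probes the same script recovered 99.50% exactly, so that a few probes can be off by a common factor. This changes their level by that factor and, by the pseudocount, their fold change, by an amount that was not tested.

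The recovered array medians were 15, 17, 23 and 18 in vehicle samples 1 to 4 and 15, 15, 16 and 15 in SKI-606 samples 1 to 4. The mean of the recovered signals after trimming 2% at each end lay between 99.82 and 99.84 in every array. Between 0.26% and 3.62% of signals were 0, and from 27.8% to 41.6% were below 10, with vehicle sample 3 at the lower end of both. The ratio of the 3' to the 5' control probe set of Actb was between 1.66 and 3.83, and that of Gapdh between 0.80 and 1.06. No detection calls, scan dates or batches were used, and none are given in the sources used here. No 2 arrays held the same values, as at least 91.7% of probes differed between any pair.

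Before the data were examined, the groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed. That plan had foreseen log2 values or intensities, not ratios. Its rule for linear values was applied to the recovered signals. Because the array medians differed by more than 0.1 on the log2 scale, signals were quantile normalized between arrays, 16 was added and log2 was taken. The log2 of the deposited ratios was added as an alternative. The test was limma 3.58.1 (lmFit and eBayes, R 4.3.3) on all 45037 probes after leaving out 64 control probes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Probe names came from the platform annotation, in which 34945 probes had 1 gene symbol, 932 had several and 9160 are unnamed here. Identifiers of 34741 of the named probes matched the gene table, and 0 symbols changed. A gene was represented by its probe with the highest mean among probes with 1 symbol, which left 18193 genes. Other probes of a named gene can give other values, as for Apod, with log2 fold changes of 2.14 and 0.19. They are given below for some genes only. Cdh5 had 0.918 and -0.065 and Myh11 0.839 and -0.187, whereas the probes of Mmp2 were alike at 1.11 and 1.148. The confidence intervals are at 95%.

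The 29 gene lists hold 764 entries, of which 698 were measured. They were tested with limma's camera on the representative probes, with a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. camera compares a list with all other genes. fry asks whether the genes of a list move one way on balance. A list score is the mean log2 value of its members in a sample, compared by a two-sided exact permutation test over all 70 assignments, whose smallest p is 0.0286. The estimated correlation between the members of the cell cycle list was 0.628 and that of the fibroblast list 0.596, far above the preset value. A further 7 lists were written after the data were seen (hair follicle keratins, late cornified epidermis, melanocyte, salivary and lacrimal gland, a clock output list, a clock list of opposite phase, and MHC class II presentation).

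Genes were named by a fixed rule. It took the 12 genes with the widest change in each direction among those past the threshold with non-overlapping groups, filled up with the genes of smallest unadjusted p where fewer qualified. It also took up to 4 members of smallest p from each list, up to 6 from a list that camera called, and the target kinases. Since 0 genes passed, all of the first 24 are of the second kind, and the text names part of the rest. Krt8, Krt18 and Cd177, and the genes of the lists written later, fall outside the rule and were chosen after their values were seen.

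The scripts were tested on simulated data drawn from the real probe means and residual spreads of this comparison. Of 100 probes changed by 1 on the log2 scale limma called 33 among 45037 simulated probes, and of 100 changed by 2 it called 91, with 1 unchanged probe called. A cell cycle list shifted by -0.5 over 18193 simulated genes without correlation was called by camera, and 0 of 28 other lists were. Alternatives were the replicate number as a block, no quantile normalization, arrays centred on their medians, dim probes left out, an intensity trend with robust estimation, array weights, a threshold of 0.1, pseudocounts of 1 and 64, a Welch test, the mean of all probes of a gene, and each sample left out in turn. Added after the data were seen were the deposited ratios, the 5 samples left without vehicle sample 3 and SKI-606 samples 1 and 4, hair keratin and muscle scores as covariates, and the exact test of list scores.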

Results

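Gene expression was measured in 8 mammary tumour samples from female mice of the MMTV-PyMT line, in which the polyoma virus middle T antigen is expressed in the mammary epithelium and tumours arise there. Of these, 4 came from mice given vehicle and 4 from mice given SKI-606 (bosutinib), an inhibitor of Src and Abl family tyrosine kinases, by mouth at 100 mg/kg. The series title names differentiation of the tumours as the question. Each sample was read on 1 Affymetrix mouse array, and the small number of arrays limits the precision of every value. The array medians of the recovered signals lay between 15 and 23. Values of single genes are log2 fold changes, SKI-606 minus vehicle, ± SE, with n = 4 in each group. They are on the scale of log2(signal + 16), which understates changes of dim genes.

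As group medians, the tumours from SKI-606 mice had lower signals of cell cycle genes and higher signals of genes of fibroblasts, blood vessels, macrophages and T cells than the vehicle tumours. SKI-606 samples 1 and 4, which stood apart over all probes and had high squamous keratin signals, as did vehicle sample 3, held much of these differences. Without these 3 samples the median log2 fold change of the cell cycle list went from -0.56 to -0.05, of the endothelial list from 0.56 to 0.15, of the macrophage list from 0.69 to 0.12, of the fibroblast list from 0.82 to 0.41 and of the T cell list from 0.56 to 0.25, and the first 2 of these lists were no longer called with the preset correlation. SKI-606 samples 1 and 4 had the highest scores of these cell type lists and the lowest of the cell cycle list. Vehicle sample 3 lay at the other end, with the lowest fibroblast, macrophage and T cell scores, 8.92, 7.47 and 4.94, and the highest cell cycle score, 7.99. Leaving these samples out therefore has to weaken the shifts and does not show their cause. At the level of single genes, none passed the test. With limma's camera test and a preset correlation 12 of 29 lists were called higher and 3 lower, and with an estimated correlation 0 were, the smallest adjusted p = 0.343 with an estimated correlation. The milk protein and alveolar secretory genes had a median of 0.03 and were not called in either direction.

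Among single genes, Apod, which encodes a secreted lipid-binding protein, had the widest difference of the 12 genes named first on the higher side, at 2.14 ± 0.35, with mean signals of 166 ± 92.3 in vehicle and 759 ± 258 in SKI-606 samples (SD, n = 4 each). Frzb, a secreted Wnt antagonist, stood at 1.53 ± 0.27, from signals near the floor in vehicle samples. Pth1r, the parathyroid hormone receptor, also dim in vehicle samples, stood at 1.20 ± 0.22, the adhesion molecule gene Vcam1 at 1.14 ± 0.20, and Cd74, the invariant chain of MHC class II, at 1.12 ± 0.19. The hedgehog co-receptor gene Boc was at 0.99 ± 0.17, the circadian transcription factor gene Dbp at 1.08 ± 0.21, and the macrophage cytokine gene Il34 at 0.82 ± 0.14. Napb, Reg1, F2rl3 and 4930486L24Rik, all dim in vehicle samples, completed the 12 higher genes, with values of 1.06 ± 0.15, 1.01 ± 0.18, 0.84 ± 0.15 and 0.93 ± 0.14. The other probes of Napb stood between -0.15 and 0.47. On the lower side, Pglyrp1, which encodes a peptidoglycan recognition protein, stood at -1.15 ± 0.23, with signals of 891 ± 273 in vehicle and 387 ± 84.9 in SKI-606 samples. The peptide transporter gene Abcb9 was at -0.98 ± 0.16, the potassium channel gene Kcnk6 at -0.86 ± 0.18, the sialyltransferase gene St8sia5 at -0.87 ± 0.19, and E2f7, a cell cycle transcription factor, at -0.78 ± 0.16. Abcb9, Kcnk6 and E2f7 were measured well above the floor in vehicle samples. C1ql3, Syn1, Usp46os2, 4930470B04Rik, Clrn1, 4930407I10Rik and Noxred1 had vehicle mean signals of at most 21.8 and log2 fold changes from -0.97 to -0.64.

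These 24 genes were those of smallest unadjusted p whose groups did not overlap, 12 in each direction. None was past the threshold, since all had an adjusted p of 0.519 in limma. Over all 45037 probes, limma called 0 higher and 0 lower, and likewise 0 of 18193 genes in either direction, at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 3771 probes, 2066 higher and 1705 lower, where 2252 are expected by chance. The corresponding number of genes was 1889, with 1105 higher and 784 lower, against 910 expected. The other limma settings tried also called 0, with 1816 to 4930 probes at an unadjusted p under 0.05, and with 2360 without SKI-606 sample 4. The 4 SKI-606 values lay all above the 4 vehicle values in 435 genes and all below in 369, together 4.42% of genes, where chance gives 2.86%.

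**Figure D1:**
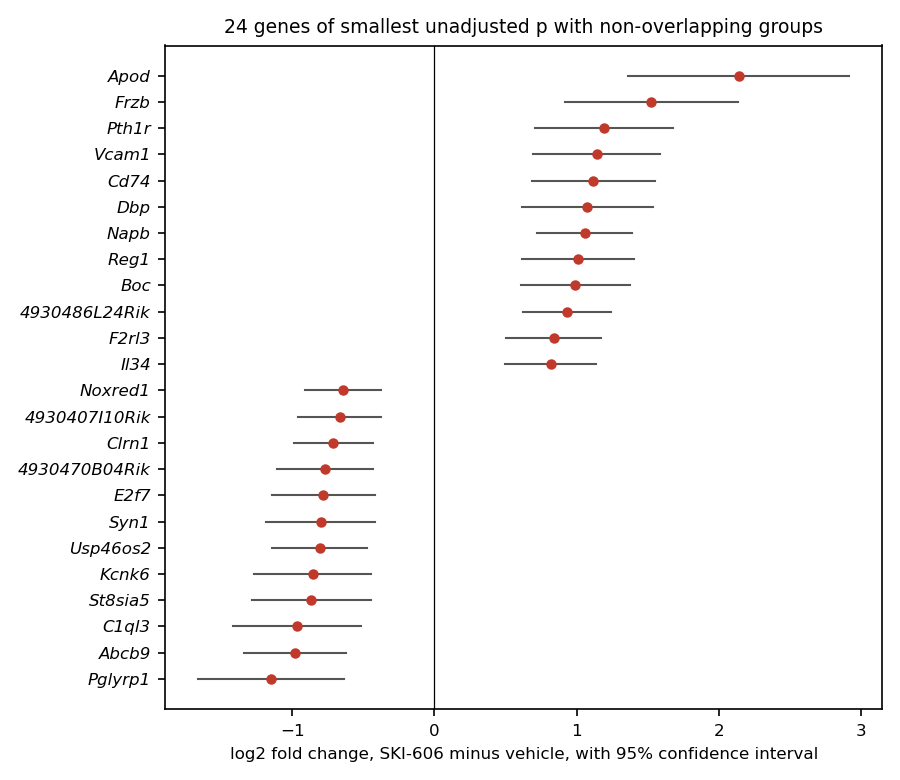
Log2 fold change (SKI-606 minus vehicle, on the log2(signal + 16) scale) of the 24 genes of smallest unadjusted p with non-overlapping groups, 12 in each direction. Points are limma estimates from 4 samples per group and lines are 95% confidence intervals, not adjusted for the number of genes tested. Apod has the highest estimate at 2.14 and Pglyrp1 the lowest at -1.15.

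Genes of the cell cycle were lower as a list in SKI-606 tumours. Of 58 measured members, 53 had a log2 fold change below 0 and 22 of these an unadjusted p under 0.05, while 0 passed when adjusted over the list alone and 0 over all genes. The cyclin genes Ccnb2 and Ccna2 stood at -0.80 ± 0.25 and -0.83 ± 0.28, the replication gene Mcm6 at -1.05 ± 0.37, and the spindle checkpoint gene Mad2l1 at -0.91 ± 0.30. The list had an adjusted p = 6.27e-13 in limma's camera test with a preset correlation, and an adjusted p = 0.405 with an estimated correlation. The mean score of the list was 7.85 ± 0.14 in vehicle and 7.32 ± 0.56 in SKI-606 samples (SD, n = 4 each), with an exact permutation p of 0.114 (two-sided). SKI-606 samples 1 and 4 had the lowest scores, 6.87 and 6.83, whereas SKI-606 samples 2 and 3, at 7.94 and 7.64, lay within the vehicle range or just below it. SKI-606 samples 1 and 4 also stood apart over all probes, with scores of 81.1 and 72.4 on a first principal component that held 34% of the variance, against -38.5 to -14.8 in the others. Vehicle sample 3 stood apart on the second component, which held 17.9%, at -81 against -2.3 to 35.2 in the others. It also had the highest array median, 23. SKI-606 samples 1 and 4 and vehicle sample 3 had the highest scores of the squamous keratinization list, 8.46, 8.49 and 8.39, against at most 6.01 in the other samples. Without these 3 samples the median of the cell cycle list was -0.05 and it was not called. Over all alternatives the adjusted p of the list ranged from 4.21e-20 to 0.542.

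Genes of fatty acid and sterol synthesis were lower as well, with a median of -0.27 over 31 members, 25 of them below 0. Thrsp, a regulator of lipogenesis, stood at -1.72 ± 0.52, the cholesterol synthesis genes Idi1, Lss and Mvd at -1.05 ± 0.36, -0.69 ± 0.22 and -0.64 ± 0.21, and Acly, which makes cytosolic acetyl-CoA, at -0.57 ± 0.22. The list's adjusted p was 1.77e-04 in camera, and the adjusted p = 0.343 with an estimated correlation. Its call ended without the 3 samples of high squamous scores, where the median was -0.09, and on the log2 of the deposited ratios, where it was -0.04. Without SKI-606 sample 1 or 4 the median was -0.17. The red blood cell list was called lower with a median of -0.28, an adjusted p = 0.0429, and an adjusted p = 0.343 with an estimated correlation. Of its 14 members 7 were measured, and 7 of 7 lay below 0. The measured members were dim, with Hbb-b2 at 27.8 ± 14.4 in vehicle and 14.4 ± 4.44 in SKI-606 samples, and Hba-a1 at -0.28 ± 0.27 on the log2 scale. The list is therefore a weak measure of red cell content. The call ended without vehicle sample 1 (median -0.19) or 4 (median -0.30) or SKI-606 sample 2 (median -0.34) or 3 (median -0.20), and also with a pseudocount of 64 (median -0.09) and with the mean of all probes (median -0.20). In 0 of these 2 lists did a member pass when adjusted over the list alone.

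Fibroblast and matrix genes were higher in SKI-606 tumours. All 25 measured members lay above 0, with a median of 0.82, and 13 passed when adjusted over the list alone, while 0 passed over all genes. Fbln1, which encodes the matrix protein fibulin-1, stood at 1.70 ± 0.38, the collagen genes Col6a3, Col6a1 and Col1a1 at 0.96 ± 0.23, 1.04 ± 0.27 and 0.85 ± 0.24, and Pdgfra, a fibroblast receptor, at 1.04 ± 0.27. The list's adjusted p was 5.72e-16 in camera and the adjusted p = 0.343 with an estimated correlation. The mean score was 9.20 ± 0.22 in vehicle and 10.05 ± 0.53 in SKI-606 samples (SD, n = 4 each), and every SKI-606 score lay above every vehicle score, with an exact permutation p of 0.0286, the smallest that 4 samples against 4 can give. The T cell list had the same exact p, while in the other 10 lists called higher the groups overlapped, with an exact permutation p of 0.0571 for the macrophage list, 0.114 for the endothelial and mesenchymal lists, 0.343 for the basal and YAP lists, and values between the first and last of these for the rest. Adjusted over the 29 lists by Benjamini-Hochberg, 0 of these exact tests passed. The smallest p of 0.0286 passes this adjustment only if many lists reach it at once, and 3 did, so this result says little. Without the 3 samples of high squamous scores the median of the fibroblast list was 0.41 and it was called with the preset correlation. The scores were then 9.85 in SKI-606 sample 2, 9.42 in SKI-606 sample 3 and at most 9.40 in vehicle samples. SKI-606 sample 2 also had a high skeletal muscle score, 8.92, and the highest adipocyte score, 8.16. The mesenchymal transition list had a median of 0.82 with 20 of 23 members above 0, and its members of smallest unadjusted p included the metalloproteinase genes Mmp3 at 1.60 ± 0.39 and Mmp2 at 1.11 ± 0.30, Tgfb1 at 0.91 ± 0.28, Sparc at 0.71 ± 0.23 and Tgfbi at 1.22 ± 0.45. Its adjusted p was 1.35e-07, and the adjusted p = 0.343 with an estimated correlation. Endothelial genes had a median of 0.56, with 24 of 26 above 0, an adjusted p of 1.01e-08, and an adjusted p = 0.343 with an estimated correlation. Among them the apelin receptor gene Aplnr stood at 1.12 ± 0.33, Sox18 at 0.99 ± 0.32, Cdh5, the cadherin of endothelial junctions, at 0.92 ± 0.33, and Pecam1 at 0.84 ± 0.27. In both of these lists 0 members passed when adjusted over the list alone. Both calls ended without the 3 samples of high squamous scores, with medians of 0.17 and 0.15.

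The macrophage and T cell lists were called higher, and the neutrophil, B cell and interferon lists were not. All 24 macrophage and dendritic cell genes lay above 0, with a median of 0.69, and 4 passed when adjusted over the list alone. Besides Cd74, the MHC class II genes H2-Ab1 and H2-Eb1 stood at 1.28 ± 0.35 and 0.60 ± 0.20, the lectin gene Mgl2 at 0.72 ± 0.16, the macrophage growth factor receptor gene Csf1r at 0.71 ± 0.19, and Adgre1, which encodes the F4/80 antigen, at 0.66 ± 0.23. The adjusted p was 8.93e-13, and the adjusted p = 0.343 with an estimated correlation. All 21 T and NK cell genes also lay above 0, with a median of 0.56, and 6 passed when adjusted over the list alone. The granzyme genes Gzmb and Gzma, of cytotoxic granules, stood at 0.99 ± 0.24 and 0.81 ± 0.22, the chemokine gene Ccl5 at 0.81 ± 0.20, Nkg7 at 0.80 ± 0.20, and the T cell genes Cd3g and Cd5 at 0.67 ± 0.17 and 0.78 ± 0.17. The adjusted p of this list was 4.60e-09, and the adjusted p = 0.343 with an estimated correlation. Its score was 5.04 ± 0.12 in vehicle and 5.53 ± 0.22 in SKI-606 samples (SD, n = 4 each), with no overlap of the groups and an exact permutation p of 0.0286. On average its members were dim, with a vehicle score near that of the red blood cell list, 4.89. The median of the T cell list was 0.33 without SKI-606 sample 4. Without the 3 samples of high squamous scores the medians of the macrophage and T cell lists were 0.12 and 0.25, and both were called with the preset correlation (adjusted p = 0.0442 and 6.71e-04). In that setting 2 samples stand against 3, and the macrophage score of SKI-606 sample 3, 8.21, lay below that of vehicle sample 1, 8.32. Over all samples the estimated correlation of the macrophage list was 0.67. In each of the fibroblast, macrophage and T cell lists 0 members passed over all genes. Neutrophil genes had a median of 0.49, with 9 of 14 above 0 and 5 below, and missed the threshold (adjusted p = 0.0534, and an adjusted p = 0.572 with an estimated correlation). Csf3r stood at 1.58 ± 0.52, Clec4d at 1.39 ± 0.42, Elane at -0.50 ± 0.20 and Cd177 at -0.68 ± 0.29. The neutrophil list was called higher without vehicle sample 3 (median 0.70) or SKI-606 sample 2 (median 0.70) or 3 (median 0.72), and also with array weights (median 0.61) and at a threshold of 0.1, while its median was 0.30 without vehicle sample 2, 0.31 without SKI-606 sample 4 and 0.04 without the 3 samples of high squamous scores. B and plasma cell genes had a median of -0.06 (adjusted p = 0.690), with Blnk at -0.73 ± 0.24. The interferon response list had a median of 0.01 (adjusted p = 0.142, and an adjusted p = 0.796 with an estimated correlation). Of its 29 members 1, the chemokine gene Cxcl9 at 1.46 ± 0.31, dim in vehicle samples, passed when adjusted over the list alone. That list was called higher without vehicle sample 4 (median 0.15) or SKI-606 sample 1 (median 0.14), and its median turned to -0.05 without vehicle sample 3 and to -0.01 without SKI-606 sample 2 or 3. The B cell median was 0.01 without SKI-606 sample 4.

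**Figure D2:**
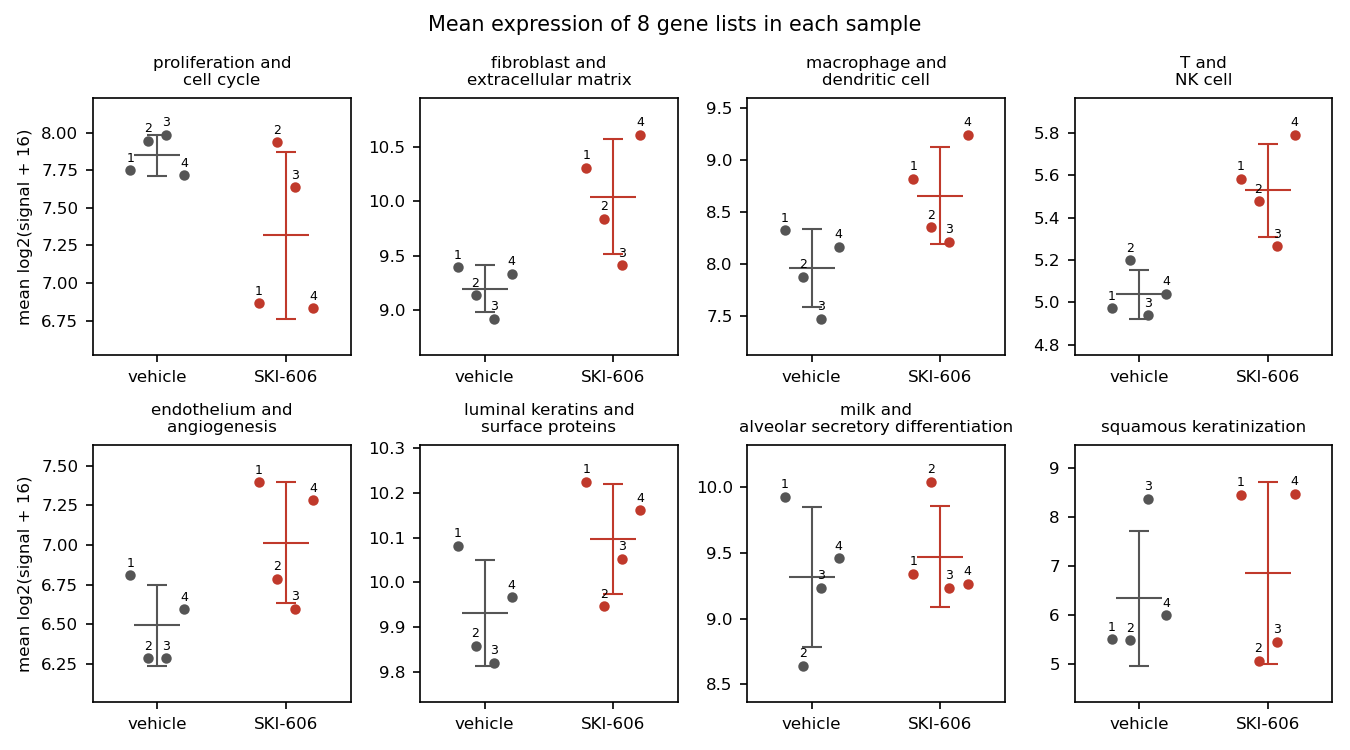
Mean log2(signal + 16) of the members of 8 gene lists in each sample, by group. Points are samples, numbered by replicate, and bars are the mean ± SD of 4 samples; vertical axes differ between panels and do not start at 0. The T and NK cell scores of SKI-606 samples, from 5.27 to 5.79, all lie above the vehicle scores, whereas the milk and alveolar scores overlap.

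The differentiation genes of the secretory epithelium were not called between the groups. Of 29 milk and alveolar genes, 15 lay above 0 and 14 below, with a median of 0.03, an adjusted p of 0.380, and 0 members past the threshold over the list alone. The casein gene Csn1s1 stood at 1.30 ± 0.50, Mfge8, which encodes lactadherin, at 0.40 ± 0.16, Cidea at 0.74 ± 0.33 and the lactoferrin gene Ltf at 0.58 ± 0.27. The score was 9.32 ± 0.53 in vehicle and 9.47 ± 0.38 in SKI-606 samples (SD, n = 4 each). With the preset correlation the call of this list hung on 1 sample, since without vehicle sample 1 its median was 0.27 and it was called higher, while over all samples it had an adjusted p = 0.813 with an estimated correlation. The median was -0.15 without vehicle sample 2, -0.001 without vehicle sample 3 and -0.08 without SKI-606 sample 2. The highest milk and alveolar scores were 10.04 in SKI-606 sample 2 and 9.93 in vehicle sample 1. Those samples also had the highest skeletal muscle scores, 8.92 and 9.36, and the highest adipocyte scores, 8.16 and 7.55. Whether other tissue in the samples moved the milk genes was not tested. The luminal keratin and surface protein list had a median of 0.05 over 20 members (adjusted p = 0.189), which was 0.03 without vehicle sample 3, 0.11 without vehicle sample 1 or 2, 0.08 without SKI-606 sample 1 and 0.15 without SKI-606 sample 2. Its keratin genes Krt8 and Krt18 stood at -0.04 ± 0.13 and -0.11 ± 0.15, Kit, a receptor of luminal progenitors, at 0.72 ± 0.22, and Krt7 at 0.70 ± 0.38, which turned to -0.004 without the 3 samples of high squamous scores. The hormone-sensing luminal list was called higher with a median of 0.21 and 12 of 15 members above 0, an adjusted p = 0.0429, and an adjusted p = 0.343 with an estimated correlation. Its members went both ways, with Tbx3 at 0.76 ± 0.24 and Prom1 at -1.22 ± 0.42, and its call ended without vehicle samples 1 or 4 or SKI-606 samples 1 or 4, with medians from 0.23 to 0.27. The call also ended without quantile normalization, with arrays centred on their medians, with dim probes left out, with a pseudocount of 64 and with the mean of all probes. It ended on the deposited ratios as well, and without the 3 samples of high squamous scores, where the median was 0.004, whereas without SKI-606 sample 3 it was 0.35. Basal and myoepithelial genes had a median of 0.59, with 16 of 19 above 0. Adjusted over the list alone 1 passed, the oxytocin receptor gene Oxtr at 1.20 ± 0.29 (0.26 with its other probe). The smooth muscle genes Myh11 and Mylk on this list stood at 0.84 ± 0.24 and 0.58 ± 0.18. The adjusted p of this list was 1.07e-04, and the adjusted p = 0.405 with an estimated correlation. Without the 3 samples of high squamous scores its median was 0.07 and it was not called, with the hair keratin score as a covariate it was 0.24 and not called, and without SKI-606 sample 2 it was 1.01. The squamous keratinization list itself had a median of 0.35 over 20 members and was not called (adjusted p = 0.359, and an adjusted p = 0.813 with an estimated correlation), with Tgm3 at 1.42 ± 0.88. With the preset correlation it was called higher without vehicle sample 3 (median 0.75) or SKI-606 sample 2 (median 0.97), and with array weights (median 0.68). It was called lower without the 3 samples of high squamous scores (median -0.23), with the hair keratin score of each sample as a covariate (median -0.59) and with hair and muscle scores (median -0.58). Its median was -0.02 without SKI-606 sample 1 or 4, 0.07 without vehicle sample 1, 0.22 without vehicle sample 2 and 0.72 without SKI-606 sample 3. Epithelial junction and polarity genes had a median of -0.01 (adjusted p = 0.740), with Crb3 at -0.51 ± 0.20, and the median was 0.05 without vehicle sample 3 or SKI-606 sample 2 and 0.02 without SKI-606 sample 1.

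Genes of the targeted kinases and of signalling pathways had list medians of at most 0.40. Src itself stood at 0.34 ± 0.17, Fyn at 0.55 ± 0.20, Yes1 at -0.46 ± 0.24, Abl1 at -0.19 ± 0.13 and Abl2 at -0.18 ± 0.18, none past the threshold, and the values of Abl1 and Abl2 changed sign with the log2 of the deposited ratios, to 0.08 and 0.10. The list of these kinases and their partners had a median of 0.21, with 15 of 19 above 0. Ctnnd1, which encodes p120 catenin, had the smallest unadjusted p of the list and stood at 0.45 ± 0.14, while the tyrosine kinase genes Ptk2b and Fgr stood at 0.68 ± 0.27 and 0.67 ± 0.32. The list's adjusted p was 0.0185, and the adjusted p = 0.343 with an estimated correlation. The call ended without vehicle sample 4 (median 0.20) or SKI-606 sample 4 (median 0.19), and without the 3 samples of high squamous scores (median 0.12). YAP and SRF target genes had a median of 0.40, with 27 of 29 above 0, an adjusted p of 2.14e-06, and an adjusted p = 0.405 with an estimated correlation. Lats2 stood at 0.79 ± 0.23, Axl at 0.99 ± 0.39, Ankrd1 at 0.71 ± 0.31 and Acta2 at 1.03 ± 0.50. Without the 3 samples of high squamous scores the median of this list was -0.008 and it was not called, and without SKI-606 sample 1 or 4 alone it was 0.19 or 0.22. Notch pathway genes had a median of 0.23 with 17 of 24 above 0, an adjusted p = 0.00270, and an adjusted p = 0.343 with an estimated correlation, with Hes1 at 0.54 ± 0.16, Notch3 at 0.42 ± 0.13 and Heyl at 0.48 ± 0.16. The immediate early list had a median of 0.22 with 22 of 32 above 0, an adjusted p = 0.0185, and an adjusted p = 0.405 with an estimated correlation. Junb stood at 0.85 ± 0.28, Klf2 at 0.83 ± 0.28 and Fos at 0.62 ± 0.29, and the call ended without vehicle sample 4 or SKI-606 samples 3 or 4, with medians from 0.12 to 0.18. The p53 and apoptosis list had a median of 0.17 with 16 of 24 above 0, an adjusted p = 0.0418, and an adjusted p = 0.446 with an estimated correlation. Phlda3 stood at 0.81 ± 0.31 and Cdkn1a, the cell cycle inhibitor p21, at 0.93 ± 0.47, and the call ended with dim probes left out (median 0.13) and without the 3 samples of high squamous scores (median 0.11). It also ended without vehicle samples 1 or 4 or SKI-606 samples 1, 3 or 4, with medians from 0.13 to 0.19. In these 5 lists 0 members passed when adjusted over the list alone. Wnt target genes had a median of 0.23 and were not called (adjusted p = 0.0633, and an adjusted p = 0.621 with an estimated correlation). Adjusted over the list alone 2 of 23 members passed, Sox9 at 0.91 ± 0.19 (0.01 and 0.42 with its other probes) and Ccn4 at 1.20 ± 0.30 (0.70 with its other probe). The list was called without vehicle sample 3 (median 0.24) or SKI-606 samples 2 (median 0.34) or 3 (median 0.30), and also without quantile normalization (median 0.20), with dim probes left out (median 0.28), with array weights (median 0.24) and at a threshold of 0.1, while its median was 0.105 without SKI-606 sample 4 and 0.06 without the 3 samples of high squamous scores.

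The remaining lists were not called. Adipocyte genes had a median of 0.18 (adjusted p = 0.256, and an adjusted p = 0.796 with an estimated correlation), with Aoc3 at 1.08 ± 0.38. With the preset correlation they were called higher without vehicle sample 1 (median 0.35) or SKI-606 sample 3 (median 0.38), and the median was 0.43 without vehicle sample 4, 0.02 without vehicle sample 2, -0.01 without vehicle sample 3 and -0.001 without SKI-606 sample 2. Skeletal muscle genes had a median of 0.21 (adjusted p = 0.577, and an adjusted p = 0.873 with an estimated correlation) and marked single samples in both groups. The score of that list was 9.36 in vehicle sample 1 and 8.92 in SKI-606 sample 2, 7.92 and 6.56 in SKI-606 sample 1 and vehicle sample 3, and at most 5.61 in the others. With the preset correlation it was called higher without vehicle sample 1 (median 1.36) or SKI-606 sample 4 (median 0.96), and its median was 0.81 without SKI-606 sample 3 and between -0.62 and -0.15 without vehicle sample 2 or 4 or SKI-606 sample 1 or 2. Nerve and Schwann cell genes had a median of -0.01 (adjusted p = 0.676), with Pmp22 at 0.87 ± 0.29. The mean of the nerve list was 0.08 and camera's direction was up, opposite to its median, which was between 0.07 and 0.23 without vehicle sample 2, 3 or 4 or SKI-606 sample 2, 3 or 4. The hypoxia and glycolysis list had a median of -0.11 (adjusted p = 0.419), with Egln3 at -1.02 ± 0.43, and the unfolded protein and stress response list -0.09 (adjusted p = 0.589), with the serine synthesis genes Phgdh and Psat1 at -1.19 ± 0.40 and -0.91 ± 0.32. Their medians were 0.09 without vehicle sample 3 and 0.02 without vehicle sample 1, in that order. Ribosomal protein genes had a median of -0.03 (adjusted p = 0.265, and an adjusted p = 0.472 with an estimated correlation), with Rpl14 at -0.53 ± 0.19. Their scores did not overlap, at 12.18 ± 0.02 in vehicle and 12.12 ± 0.03 in SKI-606 samples (SD, n = 4 each), with an exact permutation p of 0.0286, and the list was called lower without quantile normalization, with a median of -0.34, with arrays centred on their medians (median -0.22) and on the deposited ratios (median -0.10).

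In all, camera called 12 of 29 lists higher and 3 lower with the preset correlation, 0 with an estimated correlation and 0 with fry. Over all alternatives the adjusted p-values of these 15 lists ranged from 2.71e-20 to 0.808. Without vehicle sample 3 and SKI-606 samples 1 and 4 it called 5 higher and 2 lower, and the number of probes at an unadjusted p under 0.05 was 1816. Many lists share the adjusted p = 0.343 with an estimated correlation, because the adjustment gave them all the same value. Before adjustment, camera's p with an estimated correlation ran among them from 0.0128 for the T cell list to 0.118 for the mesenchymal list.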

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

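The weighing of explanations in this part used tests chosen after the results were seen, except for the count of called lists over other splits of the samples.

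A sample lay far from the others of its group in 22 of 396 groups tested, where chance flags about 1 in 20 groups, or 19.8. The value given is the gap to the nearest sample divided by the range of the group. Among vehicle samples the gap share was 0.958 for Napb, lowest in sample 4, 0.896 for 4930470B04Rik, 0.947 for Myl9, 0.928 for Cxcl9 and 0.868 for Pax5, all highest in sample 4. In vehicle sample 1 it was 0.849 for a low E2f7, 0.834 for a high Eng and 0.930 for a high Cdh5. Vehicle sample 2 was lowest for Myh11 (0.864), Epb42 (0.911) and the mesenchymal transition score (0.940). Vehicle sample 3 was lowest for Gbp2 (0.888) and highest for the neutrophil score (0.884). Among SKI-606 samples the share was 0.876 for Boc and 0.853 for Ccnb2, lowest in sample 4, and 0.857 for Pmaip1, highest there. SKI-606 sample 1 was highest for Noxred1 (0.897) and lowest for Egr1 (0.858). SKI-606 sample 2 was highest for C1ql3 (0.983) and for the milk and alveolar score (0.870), and SKI-606 sample 3 lowest for Csn1s1 (0.837) and Ltf (0.854).

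All 35 splits of the 8 samples into 4 and 4 were fitted, the real one included, and chance could not be excluded for the number of probes at an unadjusted p under 0.05, the number of called lists and the shifts of the cell cycle and milk lists. Splits were not counted for the shifts of other lists. As many probes at an unadjusted p under 0.05 as the real 3771 came from 4 of 35 splits, with 4522 the highest of the others. For probes and for genes past the adjusted threshold the real count was 0, which all 35 splits reach whatever the data, so this says nothing about chance; the highest other count was 2. As many called lists as the real 15 came from 9 splits, with up to 24 in another. A shift of the cell cycle list as wide as 0.557 came from 4 splits, with 0.704 the highest other, and one of the milk and alveolar list as wide as 0.03 from 32 splits, with 0.572 the highest other.

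SKI-606 samples 1 and 4 had the lowest cell cycle scores and also carried hair keratin RNA. Without them and vehicle sample 3 the proliferation list shift went from -0.557 to -0.052, but leaving out the lowest samples of a group has to weaken its fall, so this does not decide whether hair follicle RNA is the cause. With the hair score as a covariate the median was nearer 0, at -0.328, and was called with the preset correlation, a call that the fit without the covariate loses at an adjusted p = 0.405 with an estimated correlation, and vehicle sample 3, a single library, had the highest cell cycle score, 7.99, so hair follicle RNA is neither shown nor excluded as the cause. A lower share of epithelium in the SKI-606 samples would lower luminal genes as well. The lowest luminal keratin score of a SKI-606 sample was 0.014 above the vehicle mean, against a bound of -0.267 set after the results were seen. In SKI-606 sample 4 the members of that list went both ways. Krt7 and Aldh1a3, at 2103 and 411, lay above every vehicle value, and Krt8, Krt18 and Cldn3, at 4839, 6164 and 3068, lay below. The members also went both ways in SKI-606 sample 1. There Krt7, Krt8 and Aldh1a3, at 2371, 6337 and 277, lay above every vehicle value. Cd24a, Aqp5 and Cldn3, at 2563, 970 and 3711, lay below. The mean score therefore cannot exclude a lower share of epithelium in SKI-606 sample 1 or 4. Whether the drug acted on samples 1 and 4 alone, or these tumours differed from the others beforehand, stays open, since the design has no measure of it.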

How the results depend on the processing

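Tests on the deposited ratios, on 5 samples, with covariates and by exact scores were chosen after the results were seen. Under all alternatives, leave-outs included, limma or the Welch test called 0 probes and 0 genes in either direction, and the smallest adjusted p of a probe was 0.0743, on the deposited ratios. The count of probes at an unadjusted p under 0.05 went from 3771 to 2330 with dim probes left out, where fewer were tested, to 2293 in the Welch test and to 1816 on 5 samples, and from 2360 (without SKI-606 sample 4) to 4930 without 1 sample. The 12 lists called higher became 5 on 5 samples, and 0 with an estimated correlation, fry or the exact scores. The 3 called lower became 5 with the hair score and 5 with the hair and muscle scores as covariates, the squamous and hypoxia lists being added, and 0 with an estimated correlation, fry or the exact scores. The exact scores could hardly call a list, since their smallest p of 0.0286 passes the adjustment only if many lists reach it. The hair score also ended 5 of the 12 higher calls, hormone-sensing (0.188), basal (0.239), Src and Abl (0.153), immediate early (0.126) and p53 (0.129), and added interferon (0.191), and with the muscle score all of these but immediate early. With the replicate block 12 and 3 lists were called and 3856 probes had an unadjusted p under 0.05. The numbers did not pair the samples, with deviations correlated at 0.021, 0.108, -0.151 and -0.106 and 0 samples closest to their own number. The neutrophil list then had an adjusted p = 0.0474 and the p53 list an adjusted p = 0.0612, and no other list call changed with the block.

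The cell cycle median of -0.557 had an adjusted p = 0.405 with an estimated correlation, adjusted p = 0.287 in fry and adjusted p = 0.276 by exact scores, and the median was -0.052 on 5 samples. Over the other alternatives the proliferation list shift kept its sign and call, from -0.797 (without SKI-606 sample 2) to -0.319 (hair and muscle covariates). The milk and alveolar median of 0.03 became -0.006 without quantile normalization, -0.019 with array weights, -0.006 with a pseudocount of 64 and -0.012 with the mean of all probes. Leaving out 1 sample gave -0.145 (without vehicle sample 2) to 0.267 (without vehicle sample 1). Of 724 values of lists under alternatives, 543 kept direction and call, 91 lost the call, 30 gained it and 60 changed sign.

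On 5 samples the median changed sign for the squamous (-0.228), B cell (0.017), nerve (0.014), hypoxia (0.051), YAP and SRF (-0.008) and stress response (0.014) lists, and for Foxa1 (-0.064), Krt7 (-0.004), Dsc3 (-0.047), Cdh19 (0.014), Rhag (0.058) and Myl9 (-0.007). With the hair score as covariate it changed for squamous (-0.593), nerve (0.084) and stress response (0.066), and with hair and muscle scores for squamous (-0.584), muscle (-0.009), nerve (0.096) and stress response (0.039). With array weights it changed for junctions (0.011), muscle (-0.354), nerve (0.082) and interferon (-0.045). Without quantile normalization junctions (0.021) and interferon (-0.051) changed, and with arrays centred on medians junctions (0.148), nerve (0.078), stress response (0.039) and Abl2 (0.008). On the deposited ratios the sign changed for junctions (0.244), nerve (0.073), hypoxia (0.072), stress response (0.129), Abl1 (0.076) and Abl2 (0.096). With the mean of all probes it changed for junctions (0.007), Nr4a2 (-0.023), Abl1 (0.017) and Abl2 (0.022). It changed for nerve with dim probes left out (0.091) and with a pseudocount of 64 (0.024). Leaving out 1 sample moved squamous from -0.024 to 0.967, junctions from -0.044 to 0.050, B cell from -0.126 to 0.007, adipocyte from -0.011 to 0.428, muscle from -0.618 to 1.358, nerve from -0.071 to 0.230, hypoxia from -0.145 to 0.086, stress response from -0.099 to 0.017 and interferon from -0.051 to 0.145. The cause of these changes was not tested. Of 3860 values of 169 genes, 3848 kept their direction and 12, in 9 genes, did not. From 27.8% to 41.6% of signals per array were below 10, which limits what dim genes can show.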

Other observations

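The tests in this part were chosen after the results were seen, and all are on lists written at that point.

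Hair follicle genes were high in 3 of the 8 tumours. Their list score was 7.54 in vehicle sample 3 and 9.21 and 9.76 in SKI-606 samples 1 and 4, against 4.47 to 4.69 in the other samples. Krt27, a keratin of the inner root sheath, had signals of 816, 2413 and 3131 there and at most 12.4 elsewhere. Krt73 had 1171, 2839 and 3390, and the trichohyalin gene Tchh 1187, 1563 and 1976. Of the 26 measured members 0 reached a signal of 100 in all 8 samples, 23 reached it in at least 1, and 0 are on another list. The score overlapped between the groups, with a median log2 fold change of 1.78 and an exact permutation p of 0.429. That median was 0.96 without SKI-606 sample 1, 0.74 without SKI-606 sample 4, and 2.68 and 2.77 without SKI-606 samples 2 and 3.

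Of 10 MHC class II genes measured, of which 4 are also on the macrophage list, 9 lay above 0, with a median log2 fold change of 0.67, and Ciita, their transcriptional activator, stood at -0.14 ± 0.15. The median was 0.39 without vehicle sample 3 and SKI-606 samples 1 and 4, and 1.07 on the deposited ratios. H2-Aa stood at 1.35 ± 0.27 and Ctss, a protease of antigen processing, at 0.75 ± 0.26, and 7 members passed when adjusted over the list alone, while H2-Oa at 0.24 ± 0.17 and H2-DMb2 at 0.10 ± 0.19 did not and 0 passed over all genes. The scores did not overlap, at 7.49 ± 0.24 in vehicle and 8.15 ± 0.27 in SKI-606 samples (SD, n = 4 each). The exact permutation p was 0.0286, or 0.10 adjusted over the 7 lists. The list's adjusted p in camera was 1.75e-06, and the adjusted p = 0.173 with an estimated correlation. Among the salivary and lacrimal genes, Scgb1b27 had signals of 7871 and 6529 in vehicle samples 2 and 4 and at most 224 in the others. The median of that list was -0.24 (exact permutation p = 0.143) and moved widely, from -0.10 without SKI-606 sample 4 to -0.47 without SKI-606 sample 3, -1.24 with dim probes left out and -1.41 on the deposited ratios. The list member Car6, a secreted carbonic anhydrase, stood at -3.40 ± 0.92, and Bhlha15, a transcription factor of secretory cells, at -2.09 ± 0.70. Neither passed over all genes. Both had their lowest signals in SKI-606 samples 1 and 4, 37.4 and 35.6 for Car6 and 140.5 and 54.1 for Bhlha15. In SKI-606 sample 3 their signals, 1149.5 and 1118.5, lay within the vehicle range.

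Most clock output genes of the list with Dbp lay higher in SKI-606 tumours. The list had a median of 0.47 over 10 members, 8 above 0 and 5 past the threshold over the list alone, among them Bhlhe41 at 0.87 ± 0.19, Nr1d1 at 0.93 ± 0.24 and Tef at 0.51 ± 0.13. Nr1d1 was dim, with signals of 7.0 to 25.6 in vehicle samples. The members below 0 were Hlf, of the same transcription factor family as Dbp and Tef, at -0.53 ± 0.28, with its lowest signals in SKI-606 samples 1 and 4, 55.9 in sample 4, and 128 to 145 in vehicle samples, and Per1 at -0.02 ± 0.28. The scores did not overlap (exact permutation p = 0.0286, or 0.10 adjusted over the 7 lists), with an adjusted p = 1.03e-04 in camera and an adjusted p = 0.0706 with an estimated correlation. The median was 0.25 with the mean of all probes, 0.31 with a pseudocount of 64 and 0.81 on the deposited ratios.

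The hair follicle signal has 3 libraries on the side that SKI-606 treatment alone would not give, with vehicle sample 3 above and SKI-606 samples 2 and 3 below the middle of the range at 7.11. Skin in the dissected sample may be the source, and the late cornified list spanned 2.53 over the 8 libraries, with Lce1f at 479, 382 and 414 in the same 3 samples, and 2 of its 19 members are on another list. Its median log2 fold change was 0.47 (exact permutation p = 0.971), a sign that single libraries set, with -0.05 without SKI-606 sample 1, -0.01 without SKI-606 sample 4 and 1.25 without vehicle sample 3. The melanocyte list spanned 0.245, with a median of -0.06 (exact permutation p = 0.114) and Sox10 alone above a signal of 100, and Lor, abundant in epidermis, reached at most 101, so skin and hair-type differentiation of the tumour cells cannot be told apart here.

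The clock shift did not depend on the hair keratin libraries, since its median was 0.616 without them. That fit sets 2 samples against 3. It leaves out the lowest clock score of each group, 6.77 in SKI-606 sample 1 and 6.53 in vehicle sample 3. A difference in the time of collection could also shift the clock output genes, and would move the group of opposite phase, which had a median of -0.219 over 5 members with an exact permutation p of 0.457. That median ranged from -0.38 without vehicle sample 2 to -0.09 without vehicle sample 3, and was -0.06 with arrays centred on their medians, -0.03 with the mean of all probes and -0.004 on the deposited ratios. Of the 5 members 0 reached a signal of 100 in all 8 samples and 2 reached it in at least 1. The scale understates changes of such dim genes, so this group is a weak test. Collection time and treatment stay undecided, because the labels give no hour of collection.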
